A study of Mus musculus with 40 samples.

How the data were processed

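RNA was sequenced from sorted mouse thymocytes of 2 stages, early T-cell precursors (ETP) and double-negative 3 (DN3) cells. The 40 libraries form 12 groups, and each library is named here by its group and replicate number. The mice received 1 of 3 treatments. In the first, Zmiz1f/f mice carrying MxCre (the groups named DeltaMxCre, whose controls were mice with MxCre alone) received pI-pC, which induces MxCre. In the second, Zmiz1f/f mice with a tamoxifen-inducible Cre (DeltaTamCre, with TamCre controls) received tamoxifen. In the third, mice received either an antibody against the negative regulatory region of Notch1 (AntiNRR), which blocks Notch1, or control IgG.

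The deposited files are 3 tables of estimated counts per gene symbol, 1 column per library. Per the labels, the submitters named FastQC 0.10.0, TopHat2 2.0.9, Bowtie2 2.1.0.0, Cufflinks, Cuffdiff 2.1.1 and the mouse build mm10, without giving each tool's role or order. The labels do not state the annotation or the counting settings, so it is not known whether strand was used or how reads that match several genes were treated. The values had not been scaled between libraries. They are estimated counts in the deposited tables because between 1.21% and 1.84% of the values were further than 0.01 from a whole number, and they were rounded to whole numbers before any count test. The pI-pC and antibody table holds 23284 genes in 24 libraries, and each tamoxifen table holds 23107 genes in 8 libraries. Ribosomal-protein genes were not analysed here in the tamoxifen tables, and 25 names in the tamoxifen DN3 table have the form of a date and could match no gene list.

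Total counts per library ran from 9456818 to 23962395 in the pI-pC and antibody table, from 48127197 to 91659598 in the tamoxifen DN3 table and from 17418638 to 30975324 in the tamoxifen ETP table. Per the labels, these 3 sets were made with different library kits, so no test joined libraries of different tables. Per the labels, each pI-pC group came from 3 mice and each tamoxifen group from 4. The labels give no number of mice for the antibody groups.

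Each of the 6 comparisons used only the 2 groups it names, in R 4.3.3. Genes were kept with filterByExpr by group (minimum count 10, minimum total 15), scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 (robust dispersion and robust fit), with group as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are deleted or treated minus control, fitted with a prior count of 0.125. Levels are CPM, the counts scaled to a common library size by TMM, given as mean ± SD over the libraries of a group. The differences between effects were tested in 4 interaction models within the pI-pC and antibody table. The effects of tamoxifen in ETP and in DN3 were not tested against each other, since their kits differ. The overlap of calls between comparisons of the same stage was tested by Fisher's exact test, two-sided, over the genes tested in both, with Benjamini-Hochberg adjustment over 6 tests.

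The 22 gene lists were tested with camera in limma 3.58.1 with the preset correlation of 0.01, adjusted over the lists of a comparison with at least 5 tested members. They are Notch target genes, Notch transcription complex and Zmiz1 family, Myc targets, cytosolic ribosomal proteins, DNA replication (S phase), mitosis (G2 and M phase), T-lineage genes, stem and progenitor genes, B-cell markers, myeloid markers, dendritic-cell markers, natural killer and innate lymphoid markers, gamma-delta T-cell markers, double-positive thymocyte markers, mature T-cell markers, erythroid markers, thymic stromal markers, p53 target genes, type I interferon response, integrated stress and unfolded protein response, glycolysis, and immediate early genes. Some genes stand in more than 1 list, such as Ptcra among the Notch target and T-lineage genes. Members past the threshold were counted over all genes tested and also adjusted over the list alone. Camera with an estimated correlation and fry were run as alternatives.

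Genes were chosen for naming by a rule. It takes Zmiz1, Notch1, Myc, Hes1, Dtx1, Nrarp, Notch3, Il2ra and Ptcra in every comparison. It adds the 6 largest rises and the 6 largest falls among called genes with a mean of at least 5 CPM and no overlap between the groups, leaving out gene models named Gm, Rik, -ps or LOC, microRNAs, small RNAs and receptor segments. It adds the 3 members with the lowest p in the direction of each called list, and the 4 genes with the lowest p in each interaction. The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. Genes named outside the rule are said to have been chosen after their values were seen. Gene positions are from GENCODE M21 on GRCm38 and were matched by symbol.

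The alternatives were the Wald test of DESeq2 1.42.0, DESeq2 size factors in place of TMM, no filter beyond 1 count, a filter at a mean of 10 counts, a replicate block, removal of ribosomal RNA and hemoglobin genes (the tables hold no mitochondrial genes), a spread shared by all 4 groups of a stage, a test against a fold of 1.2, and leaving out each library in turn. The overlaps were also computed at an adjusted p under 0.1, with DESeq2 calls, and with a fold of at least 1.5. Added after the data were seen were voom with library weights, the level of Cd8a as a covariate in both tamoxifen comparisons, the level of Malat1 as a covariate in DN3 pI-pC, and the tamoxifen DN3 comparison lacking libraries 1 and 2 of both groups. For ETP the values with the Cd8a covariate enter only the tallies of alternative values and are not given singly.

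The tests of edgeR and DESeq2, camera with its preset correlation and the interaction models were run on simulated data with known changes, while fry, Fisher's test and the library-weighted test were not, and the data were drawn from the means and library sizes of each comparison. Each gene was drawn independently, so camera was not checked under correlation between genes. At a simulated fold of 4, edgeR called 63.6% of the changed genes in the ETP pI-pC design, 77.3% in DN3 pI-pC, 65.2% in ETP tamoxifen, 90.9% in DN3 tamoxifen, 72.7% in ETP antibody and 74.2% in DN3 antibody. At a fold of 1.5 the shares were 1.49%, 8.96%, 2.99%, 50.7%, 4.48% and 23.9% in the same order. Unchanged genes called by edgeR numbered 4, 13, 7, 6, 8 and 11, and those called by DESeq2 numbered 31, 35, 35, 29, 28 and 20. DESeq2 called 6, 13 and 47 changed genes at folds of 1.5, 2 and 4 in ETP pI-pC. It called 10, 36 and 55 in DN3 pI-pC and 6, 31 and 51 in ETP tamoxifen. In every design unchanged genes made up a larger share of the DESeq2 calls than of the edgeR calls. For DESeq2 that share exceeded the adjusted p threshold in every design, and for edgeR in all but DN3 tamoxifen. Calls by DESeq2 alone are therefore weaker evidence. These simulations ran on 11594, 12389, 12668, 13142, 12176 and 12349 genes.

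Intervals and floors cover counting error only, since reads from amplified libraries are not independent molecules. A fold against a group with 0 counts is given against a floor of 3 counts over the group. Where the floxed part of Zmiz1 lies is not given in the labels, and the gene-level count includes the exons that remain, so a remaining Zmiz1 count does not measure the share of undeleted cells.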

Results

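RNA was sequenced from mouse thymocytes sorted as early T-cell precursors (ETP) or as double-negative 3 (DN3) cells, in 40 libraries and 12 groups. Zmiz1, a transcriptional co-activator of Notch1, was deleted in Zmiz1f/f mice with pI-pC (MxCre, libraries made 8 weeks later, 3 per group) or with tamoxifen (TamCre, 4 per group). The controls carried the Cre alone and received the same agent. In another experiment an antibody that blocks Notch1 (AntiNRR) was set against control IgG (3 libraries per group). The comparisons ask which genes change when Zmiz1 is lost or Notch1 is blocked at each stage. Total counts per library ran from 9456818 to 14385245 in IgG ETP, 13544135 to 16283070 in AntiNRR ETP, 15277568 to 18745922 in IgG DN3 and 11695668 to 18395358 in AntiNRR DN3. They ran from 16985331 to 23962395 in MxCre ETP, 15530100 to 17064846 in DeltaMxCre ETP, 16537447 to 19133149 in MxCre DN3 and 12829780 to 18348755 in DeltaMxCre DN3. The tamoxifen groups held 21326502 to 30975324 counts in TamCre ETP, 17418638 to 24633744 in DeltaTamCre ETP, 65053364 to 91659598 in TamCre DN3 and 48127197 to 66487249 in DeltaTamCre DN3.

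The labels give the same CD44 and CD25 phenotype to both sorted stages, so stage marker levels were compared as CPM, mean ± SD over libraries. Cd44, an adhesion receptor of early precursors, stood at 134 ± 41.4 CPM in MxCre ETP and at 5.51 ± 1.71 in MxCre DN3. Ptcra, the pre-T-cell receptor alpha chain, stood at 3.63 ± 2.57 CPM in MxCre ETP and at 161 ± 34.2 in MxCre DN3. In TamCre libraries Cd44 was at 153 ± 31.4 CPM in ETP and 4.23 ± 0.994 in DN3, from separate kits, and in IgG libraries it was at 89.6 ± 44.9 in ETP and 2.63 ± 0.253 in DN3. Il2ra, which encodes CD25, was not low in ETP, at 1820 ± 286 CPM in MxCre ETP against 3310 ± 967 in MxCre DN3. These levels were compared as values and not tested.

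Zmiz1 (chromosome 14, 25459185 to 25666743, plus strand, GRCm38) was lower in each deleted library than in each control library of its comparison. In ETP after pI-pC, the DeltaMxCre libraries held 54, 89.4 and 106 CPM and the MxCre libraries 298, 223 and 142. In DN3 after pI-pC, they held 119, 130 and 114 CPM against 288, 354 and 322. In ETP after tamoxifen, the DeltaTamCre libraries held 174, 120, 307 and 202 CPM and the TamCre libraries 424, 418, 461 and 458. In DN3 after tamoxifen, they held 201, 243, 184 and 188 CPM against 354, 323, 301 and 312. The antibody libraries held 252, 235 and 98.8 CPM in ETP (IgG 227, 214 and 207) and 333, 319 and 331 in DN3 (IgG 317, 293 and 267). The fall of Zmiz1 passed the edgeR test in DN3 after pI-pC (log2 fold change -1.41, SE 0.131, adjusted p = 0.000144) and in DN3 after tamoxifen (-0.66, SE 0.0971, adjusted p = 0.0368). It did not pass edgeR in ETP after pI-pC (-1.41, adjusted p = 0.256) or after tamoxifen (-1.13, SE 0.23, adjusted p = 0.907), where DESeq2 gave adjusted p = 0.00269 and 0.0076.

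**Figure D1:**
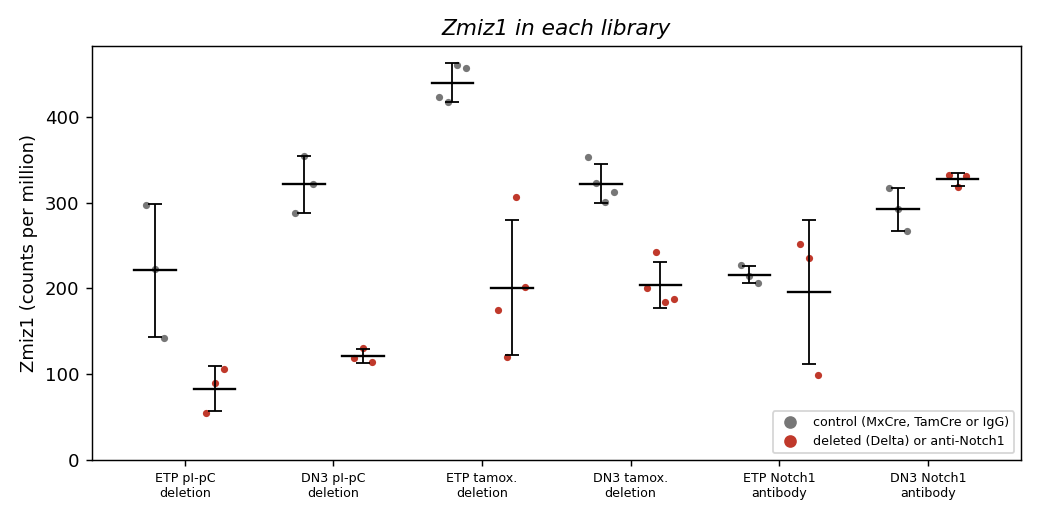
Zmiz1 in each library (counts per library scaled to CPM, y axis) for the 6 comparisons (x axis), with grey points for controls, red points for deleted or antibody-treated libraries, a line at the mean and bars of 1 SD. In each of the 4 deletion comparisons all deleted libraries lie below all controls, with 121 against 321 CPM on average in DN3 after pI-pC.

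In ETP after pI-pC deletion of Zmiz1, edgeR called 5 of 12010 genes, all higher, with 326 higher and 342 lower at an unadjusted p under 0.05. These unadjusted counts are little above the share of 0.05 that chance alone gives. DESeq2 called 43 higher and 43 lower. Dtx1, a Notch target that encodes the ubiquitin ligase Deltex1 (chromosome 5, 120680202 to 120711927, minus strand), rose 9.08-fold, from 18 ± 9.7 to 163 ± 33.4 CPM (log2 fold change 3.18, SE 0.392). Ptcra (chromosome 17, 46755663 to 46763712, minus strand) rose 11.8-fold, from 3.63 ± 2.57 to 43 ± 15.2 CPM, and Il2ra (chromosome 2, 11642807 to 11693193, plus strand) rose 2.41-fold, from 1820 ± 286 to 4380 ± 235 CPM. Bst1, a surface ADP-ribosyl cyclase (chromosome 5, 43818885 to 43843986, plus strand), rose from 12.5 ± 5.26 to 72.8 ± 11.5 CPM. Cdh1, which encodes E-cadherin (chromosome 8, 106603351 to 106670246, plus strand), rose from 44.2 ± 15.3 to 167 ± 29.3 CPM. The edgeR adjusted p was 0.0185 for Dtx1, 0.0493 for Ptcra and 0.0362 for Il2ra, Bst1 and Cdh1. A spread shared by all 4 ETP groups called 7 genes, of these 5 only Bst1 and Cdh1, and ended the calls of Dtx1 (adjusted p = 0.416), Il2ra (0.316) and Ptcra (0.164). Leaving out any DeltaMxCre ETP library ended all 5 calls, and leaving out MxCre ETP 2 left 1. Leaving out MxCre ETP 1 or 3 gave 17 or 10 calls.

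Among the gene lists in ETP after pI-pC, Notch target genes were shifted higher (median log2 fold change 0.44, camera adjusted p = 7.39e-08), with an adjusted p = 0.0937 with an estimated correlation. Of the 13 members 3 rose and 0 fell by edgeR, 4 rose and 0 fell by DESeq2, and adjusted over the list alone 6 rose and 1 fell by edgeR. Notch1 (1890 ± 31.8 against 1180 ± 386 CPM, edgeR adjusted p = 0.649), Notch3 (320 ± 11.9 against 153 ± 65.8, 0.403) and Hes1 (63.3 ± 4.85 against 40.3 ± 6.8, 0.822) did not pass edgeR, while Notch3 passed DESeq2 (0.0192), and Myc and Nrarp had log2 fold changes of -0.10 and 0.33. T-lineage genes (median 0.32, adjusted p = 0.000523, and 0.0937 with an estimated correlation) held 1 member that rose by edgeR, Ptcra, with 2 by DESeq2 and 2 adjusted over the list alone. Rag1, of receptor gene recombination, had 619 ± 89.1 against 234 ± 130 CPM (edgeR adjusted p = 0.403, DESeq2 0.00369), and Cd3e a log2 fold change of 0.62. Thymic stromal markers (median 1.00, adjusted p = 0.000523, and 0.0937 with an estimated correlation) had 1 of 7 risen, Cdh1, with Epcam at a log2 fold change of 0.95. Col1a2 had 56 counts in DeltaMxCre ETP and 0 in MxCre ETP, at least 21.6-fold higher against 3 counts over the group. Stem and progenitor genes were shifted lower (median -1.13, adjusted p = 1.02e-16, and 0.0937 with an estimated correlation), with all 18 members below 0. Over all genes edgeR called 0 of them and DESeq2 5, all lower, and 9 fell by edgeR adjusted over the list alone. Cd34, a stem and progenitor surface protein, had 35.3 ± 17.9 against 132 ± 26.9 CPM (edgeR adjusted p = 0.141, DESeq2 0.000304), Cd44 had 55.2 ± 11.5 against 134 ± 41.4 (0.252, DESeq2 0.00646) and Bcl11a, a progenitor transcription factor, a log2 fold change of -1.47 (0.252, DESeq2 0.00957).

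Other lists shifted lower in these ETP were immediate early genes (median -1.12, camera adjusted p = 5.6e-06), natural killer and innate lymphoid markers (-0.95, 0.00377), myeloid markers (-0.83, 0.0074), glycolysis (-0.30, 0.00377) and cytosolic ribosomal proteins (-0.21, 0.000214). Their adjusted p ran from 0.518 to 0.777 with an estimated correlation. The type I interferon response was shifted higher (0.22, 0.0158, and an adjusted p = 0.697 with an estimated correlation). No member of these 6 lists passed edgeR over all genes, DESeq2 called 2 myeloid, 1 natural killer and 1 immediate early gene lower, and adjusted over the list alone 1 member fell in each of the immediate early, natural killer and myeloid lists. Mpo, a granule enzyme of myeloid cells, had 24.8 ± 17 against 115 ± 65.6 CPM, Gzma, a killer-cell protease, had 19.8 ± 9.1 against 80.6 ± 48, and Dusp1, a phosphatase gene of the early response, had 5.46 ± 1.11 against 27 ± 16.5. Tyrobp, Il2rb, Il1rl1, Egr1 and Zfp36 had log2 fold changes of -2.86, -1.96, -0.95, -3.02 and -2.72, and Fcgr3 had 1 count in all against 266. Rtp4, an interferon-induced gene, had 46.4 ± 12 against 19.3 ± 10.3 CPM. Gpi1, Tpi1 and Slc2a3 of glycolysis had -0.49, -0.56 and -1.14, and Rps18 and Rps4x had -0.43 and -0.43. Without MxCre ETP 3 the ribosomal (adjusted p = 0.973), interferon (0.698) and glycolysis (0.421) shifts did not pass, without MxCre ETP 2 the natural killer (0.55), immediate early (0.102) and myeloid (0.0668) shifts did not, and without DeltaMxCre ETP 2 the myeloid (0.0918) and interferon (0.0888) shifts did not. The other 11 lists did not pass (adjusted p from 0.0696 to 0.961), among them Myc targets with a median of -0.07.

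In DN3 cells, pI-pC deletion of Zmiz1 changed 183 of 12675 genes in edgeR, 125 up and 58 down, and 527 in DESeq2, 318 up and 209 down. Dtx1 rose from 168 ± 29.7 to 369 ± 15.8 CPM (log2 fold change 1.13, SE 0.142, adjusted p = 0.00115). Evl, a regulator of actin filaments (chromosome 12, 108554720 to 108688516, plus strand), rose from 11.5 ± 2.66 to 53.7 ± 7.77 CPM (2.22, SE 0.227, adjusted p = 0.000273). Other large rises were Phxr4 (log2 fold change 2.47), the glycosyltransferase B4galnt2 (2.23), the cytokine receptor Il31ra (2.17), the gamma-glutamyl transferase Ggt5 (1.93) and Cish, an inhibitor of cytokine signalling (1.87). Hoxa7, a homeobox factor of progenitors (chromosome 6, 52214491 to 52221854, minus strand), fell from 23.3 ± 5.99 to 3.34 ± 0.911 CPM (adjusted p = 0.00115), and Fat4, a large cadherin (chromosome 3, 38886940 to 39011985, plus strand), fell from 20.9 ± 11.6 to 1.37 ± 0.626 (0.0019). Further falls were Cttn (-2.22), Maged1 (-2.18), Cdc42ep4 (-2.13) and the Hippo pathway adaptor Sav1 (-2.02). Myc (86.3 ± 16.8 against 154 ± 66.3 CPM) had an edgeR adjusted p = 0.211 and a DESeq2 one of 0.0209, and Il2ra (4990 ± 738 against 3310 ± 967) had 0.158 and 0.0395. Notch1 (2870 ± 114 against 2870 ± 261 CPM), Ptcra (181 ± 19.1 against 161 ± 34.2), Notch3 (log2 fold change -0.35), Hes1 (0.20) and Nrarp (0.55) did not pass.

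Gene groups of growth were shifted lower in these DN3 cells, none of them passing with an estimated correlation. Myc targets had a median log2 fold change of -0.28 over 58 genes, 51 of them below 0 (camera adjusted p = 2.72e-09, and 0.352 with an estimated correlation), with 1 fallen over all genes, the nucleolar Nop56 (167 ± 14.4 against 253 ± 16.7 CPM), and 10 adjusted over the list alone. Ipo4 and Rcl1 had -0.62 and -0.67. Cytosolic ribosomal proteins had a median of -0.32, with 72 of 77 below 0 (1.76e-14, and an adjusted p = 0.352 with an estimated correlation), 2 fallen, Rpsa (2440 ± 376 against 3950 ± 749 CPM) and Rps19 (-0.64), and 18 adjusted over the list alone, while Rpl13a had -0.51. Glycolysis (-0.26, 0.00406, and an adjusted p = 0.401 with an estimated correlation) had 0 fallen by edgeR, 2 by DESeq2 and 5 adjusted over the list alone, with Tpi1 at -0.65 and Hk2 at -0.70. S-phase genes (-0.25, 0.00613), such as Mcm7 at -0.46, and immediate early genes (-0.64, 0.0096), such as Egr1, Ier2 and Nr4a1 at -0.78, -0.89 and -0.91, had 0 fallen by either edgeR count or by DESeq2. For these 2 lists the adjusted p with an estimated correlation was 0.721 and 0.401. Malat1, a nuclear RNA, took 1.18 ± 0.194% of counts in DeltaMxCre DN3 and 0.573 ± 0.216% in MxCre DN3, and the ribosomal precursor Rn45s took 4.88 ± 0.181% and 7.75 ± 1.03%. With Malat1 as a covariate, chosen after the data were seen, the Myc target shift did not pass (camera adjusted p = 0.239), S phase was shifted higher (mean log2 fold change 0.504, adjusted p = 6.99e-09), glycolysis turned to 0.0529 (0.4) and immediate early genes did not pass (0.69). Stem and progenitor genes were also lower (-0.26, 0.00613, and an adjusted p = 0.352 with an estimated correlation), and their 3 fallen members were Hoxa7, Bcl11a (5.86 ± 1.42 against 23.6 ± 7.61 CPM) and Cd44 (0.657 ± 0.103 against 5.51 ± 1.71).

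Groups shifted higher in DN3 after pI-pC deletion were the type I interferon response (median 0.76, 22 of 23 above 0, camera adjusted p = 4.47e-08), mature T-cell markers (0.47, 0.00323) and double-positive thymocyte markers (0.24, 0.0396). Each had an adjusted p = 0.352 with an estimated correlation. Over all genes edgeR called 0 interferon genes and DESeq2 4, all higher, and 8 rose by edgeR adjusted over the list alone. The interferon-induced Usp18 had 27.7 ± 2.41 against 14.2 ± 4.35 CPM (edgeR adjusted p = 0.0779, DESeq2 0.0185), and Ddx58 and Zbp1 had log2 fold changes of 0.59 and 0.87. Ms4a4b, a surface protein of mature T cells, rose from 5.73 ± 3.08 to 20.2 ± 2.34 CPM, as 1 of 11 (3 adjusted over the list alone). Themis, a signalling protein of T-cell selection, rose from 420 ± 41.7 to 624 ± 48.4 CPM, as 1 of 13 (4 adjusted over the list alone), with Plxnd1 and Arpp21 at 0.71 and 0.56. Notch target genes did not pass (adjusted p = 0.822). Their median log2 fold change was -0.05 while camera's direction was up, and by edgeR 2 of 16 rose and 0 fell. DESeq2 called 3 higher and 3 lower, and adjusted over the list alone edgeR called 3 higher and 4 lower. The edgeR risers were Dtx1 and the pseudokinase Trib2 (59.9 against 21.6 CPM, chosen after its values were seen). The other 11 lists did not pass either (from 0.0978 to 0.923).

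Zmiz1, Dtx1, Evl, Hoxa7, Fat4 and Sav1 kept their DN3 pI-pC calls without any single library. A spread shared by all 4 DN3 groups ended those of Dtx1 (edgeR adjusted p = 0.1), Il31ra (0.297) and Cttn (0.115). Without DeltaMxCre DN3 3, 2 or MxCre DN3 1, edgeR called 12, 15 or 81 genes, and without MxCre DN3 3 it called 403. DeltaMxCre DN3 2 or 3, left out, ended the calls of Phxr4, B4galnt2, Il31ra, Ggt5, Cttn, Cdc42ep4, Bcl11a, Cd44, Nop56, Rpsa, Rps19, Ms4a4b and Themis, DeltaMxCre DN3 2 that of Cish and DeltaMxCre DN3 3 that of Maged1. Without DeltaMxCre DN3 1, stem genes (adjusted p = 0.0873), immediate early genes (0.069) and double-positive markers (0.069) did not pass. Without MxCre DN3 3, S phase (0.911, with a direction of up), glycolysis (0.113) and immediate early genes (0.171) did not. S phase was also lost without DeltaMxCre DN3 2 or 3 (0.0602 and 0.067), and double-positive markers without DeltaMxCre DN3 2, MxCre DN3 1 or MxCre DN3 2 (0.109, 0.126 and 0.153).

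After 43 to 44 hours of tamoxifen deletion in ETP, edgeR called 0 of 12924 genes (lowest adjusted p 0.907), with 640 at an unadjusted p under 0.05 (343 up, 297 down) and 2 called by DESeq2. The 640 are about the share of 0.05 that chance alone gives. Dtx1 had 125 ± 15.9 CPM in DeltaTamCre and 76 ± 11.7 in TamCre libraries (log2 fold change 0.72, SE 0.148, DESeq2 adjusted p = 0.0504). Myc had 171 ± 30 against 213 ± 7.68 CPM, Il2ra 1860 ± 705 against 2030 ± 87.1 and Ptcra 10.1 ± 8.43 against 7.84 ± 3.68. Notch1, Notch3, Hes1 and Nrarp had log2 fold changes of 0.01, 0.16, -0.10 and 0.35. Markers of later thymocytes varied within both groups, with Cd8a from 16.9 to 342 CPM in DeltaTamCre and from 10.2 to 178 in TamCre, and Rag1 from 97.3 to 2630 and from 72 to 1280.

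Cell-cycle and growth genes were shifted lower in these tamoxifen ETP as lists, with 0 members of these or the other shifted lists past edgeR or DESeq2. Malat1 took 0.927 ± 0.383% of counts in DeltaTamCre ETP and 0.526 ± 0.147% in TamCre ETP. Mitosis genes had a median of -0.36 with all 25 below 0 (camera adjusted p = 3.68e-12), S-phase genes -0.25 with 29 of 30 below 0 (2.35e-07) and Myc targets -0.19 with 49 of 58 below 0 (1.32e-05). Each had an adjusted p = 0.895 with an estimated correlation. The spindle checkpoint kinase Ttk had 10.3 ± 3.21 against 18.8 ± 3.97 CPM and the kinetochore protein Cenpf 148 ± 45.6 against 228 ± 33.6, with Bub1 at -0.59. The replication genes Pola1, Chaf1a and Lig1 had -0.36, -0.41 and -0.43. Gnl3, a nucleolar protein among the Myc targets, had 66.6 ± 7.83 against 83.2 ± 5.04 CPM, with Rrp9 and Dctpp1 at -0.37 and -0.48. Immediate early genes (0.53, 0.0111), type I interferon genes (0.20, 0.0146) and dendritic-cell markers (0.20, 0.0352) were shifted higher, with an adjusted p = 0.9, 0.9 and 0.895 with an estimated correlation. Among them Btg2 had 149 ± 66.7 against 91.8 ± 10.8 CPM and Itgax, which encodes CD11c, 21.8 ± 7.81 against 9.37 ± 1.84. Adjusted over the list alone 1 dendritic-cell marker rose and no member of the other 5 lists changed.

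Several of these list shifts depended on single libraries, and without DeltaTamCre ETP 1 or 2 edgeR called 1 gene. Without DeltaTamCre ETP 1 the S-phase (adjusted p = 0.219), interferon (0.178) and immediate early (0.881) shifts did not pass and Notch target genes did (0.025). Without DeltaTamCre ETP 2 the interferon (0.255) and dendritic (0.137) shifts did not pass, nor did the dendritic one without DeltaTamCre ETP 3 (0.347). Without TamCre ETP 3 the immediate early (0.268) and dendritic (0.15) shifts were lost, and without TamCre ETP 4 these 2 (0.0858 for both) and the interferon shift (0.964). With all libraries Notch target genes had a median of 0.01 (0.687), and they and the other 14 lists did not pass (from 0.158 to 0.834).

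In DN3 after tamoxifen deletion, 11 of 13298 genes changed in edgeR, 7 up and 4 down, and 458 in DESeq2, 244 up and 214 down. Evl rose from 13.1 ± 0.923 to 26.6 ± 3.35 CPM (log2 fold change 1.02, SE 0.109, adjusted p = 0.00827) and Il31ra from 8.25 ± 0.403 to 16.4 ± 1.62 (0.99, SE 0.108, adjusted p = 0.00827). Jakmip1, which binds Janus kinases, rose from 26 ± 1.81 to 44 ± 4.19 CPM, Ggt5 from 3.49 ± 0.266 to 7.48 ± 1.37, and Myl4 and Itgb3, a myosin light chain and an integrin chain, by 0.69 and 0.67 on the log2 scale. The tetraspanin Cd53, the other riser (0.64, adjusted p = 0.0488), was named after its values were seen. Besides Zmiz1, the genes that fell were Gzma (229 ± 11.5 to 141 ± 23 CPM), Pgam2 (42.2 ± 1.53 to 22.9 ± 4.48) and Qsox2 (71.9 ± 4.75 to 50.3 ± 3.33). Myc had 463 ± 72.6 against 626 ± 28.2 CPM (log2 fold change -0.43, edgeR adjusted p = 0.128, DESeq2 0.0096). Dtx1 (586 ± 74.5 against 498 ± 57.4 CPM, edgeR adjusted p = 0.336), Il2ra (log2 fold change 0.22), Ptcra (0.07), Notch1 (-0.05), Notch3 (-0.11), Hes1 (-0.09) and Nrarp (0.22) did not pass.

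Myc targets were shifted lower in these DN3 cells, with a median of -0.23 and 55 of 58 below 0 (camera adjusted p = 1.57e-19, and 0.176 with an estimated correlation), 0 called by edgeR over all genes, 6 called lower by DESeq2 and 27 fallen by edgeR adjusted over the list alone. Nop16, a nucleolar protein, had 55.8 ± 1.98 against 71.6 ± 5.01 CPM (edgeR adjusted p = 0.107, DESeq2 0.00213), and Mrto4 and Dctpp1 had -0.34 and -0.40. Glycolysis genes were lower (-0.25, 3.18e-06, and an adjusted p = 0.379 with an estimated correlation), with 4 called by DESeq2, 5 fallen adjusted over the list alone and Ldha at 722 ± 77 against 944 ± 133 CPM, Pfkl at -0.32 and Tpi1 at -0.38. S-phase genes were lower by a smaller median (-0.11, 0.00523, and an adjusted p = 0.853 with an estimated correlation). Lists shifted higher were dendritic-cell markers (0.39, 0.0275), B-cell markers (0.35, 0.00523), myeloid markers (0.31, 0.0201) and stem and progenitor genes (0.22, 0.00523). With an estimated correlation the adjusted p was 0.176 for the first 3 of these lists and 0.292 for stem genes. Their counts adjusted over the list alone were 2, 1, 3 and 0, and over all genes edgeR called none of their members and DESeq2 2, 1, 2 and 0 higher. The transcription factor Spib, of B and plasmacytoid dendritic cells, had 97.4 ± 5.96 against 60.8 ± 14 CPM (DESeq2 adjusted p = 0.00176), Itgam 1.91 against 0.76 and Tyrobp 0.834 ± 0.217 against 0.267 ± 0.0747, while Runx2, Kit and Erg had log2 fold changes of 0.41, 0.33 and 0.35. The other 14 lists did not pass (from 0.0559 to 0.993), and Notch target genes had a median of -0.07 (0.935).

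**Figure D2:**
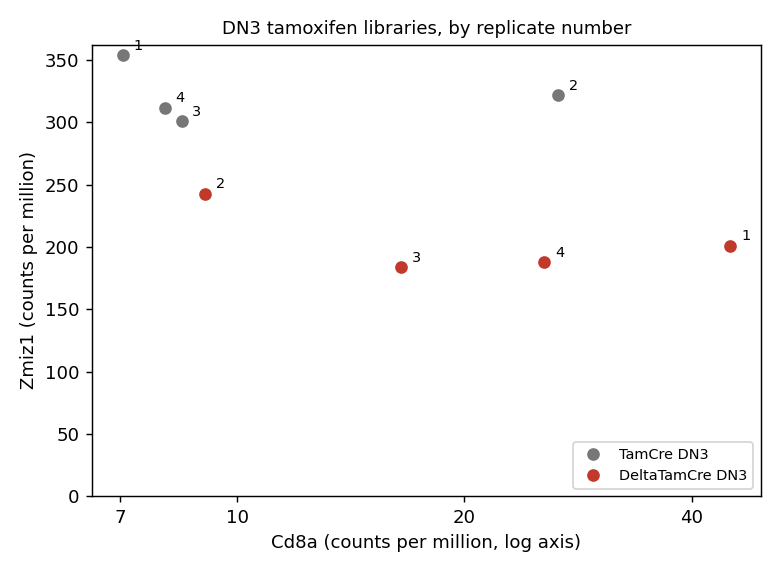
Cd8a (CPM, log axis) against Zmiz1 (CPM) in the 8 DN3 tamoxifen libraries, 1 point per library with its replicate number. DeltaTamCre DN3 1, 3 and 4 and TamCre DN3 2 lie at 16.5 to 45 CPM of Cd8a, and the other 4 libraries at 7.05 to 9.08.

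The DN3 tamoxifen libraries were also divided by Cd4 and Cd8a, co-receptors of later thymocytes. Cd8a stood at 45, 16.5 and 25.5 CPM in DeltaTamCre DN3 1, 3 and 4 and at 26.6 in TamCre DN3 2, but at 9.08 in DeltaTamCre DN3 2 and at 7.05, 8.44 and 8.02 in TamCre DN3 1, 3 and 4. With Cd8a as a covariate, chosen after the data were seen, edgeR called 13 genes, 7 of them shared with the 11. The calls of Zmiz1, Ggt5, Pgam2 and Qsox2 then ended, the Myc target shift passed (camera adjusted p = 3.49e-11) and the S-phase shift did not (0.501). Without 1 library edgeR called from 0 (TamCre DN3 3 or 4) to 8 genes (DeltaTamCre DN3 1). DeltaTamCre DN3 4, TamCre DN3 1, DeltaTamCre DN3 3, DeltaTamCre DN3 2 and TamCre DN3 2 left out gave 1, 2, 4, 5 and 6. Zmiz1 was called only with DeltaTamCre DN3 2 as the library left out, while Evl lost its call without TamCre DN3 3 or 4 and Il31ra without these or DeltaTamCre DN3 4. Dendritic-cell markers did not pass without DeltaTamCre DN3 1 or 2 or TamCre DN3 2 or 3 (adjusted p = 0.0615, 0.0781, 0.107 and 0.0559), S phase without DeltaTamCre DN3 3 or 4 (0.0559 and 0.138) and myeloid markers without TamCre DN3 3 (0.0634).

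After 24 hours of Notch1 antibody in ETP, edgeR called 0 of 12568 genes (lowest adjusted p 0.0816), with 687 at an unadjusted p under 0.05 (328 up, 359 down) and 28 called by DESeq2. The 687 are little above the share of 0.05 that chance alone gives. Notch1 had 839 ± 109 CPM against 1530 ± 137 (log2 fold change -0.87, SE 0.158, edgeR adjusted p = 0.139, DESeq2 2.32e-05) and Notch3 82.7 ± 39.1 against 227 ± 75.8 (DESeq2 0.00471). Dtx1 had 3.22 ± 4.72 against 26.1 ± 1.77 CPM, Il2ra 580 ± 404 against 2190 ± 376, Ptcra 6.26 ± 7.93 against 33.5 ± 8.27 and Myc 74.6 ± 30.9 against 149 ± 27. Hes1 and Nrarp had log2 fold changes of -0.35 and -0.15. AntiNRR ETP 3 stood above the other antibody libraries, with 8.65 CPM of Dtx1 against 0.941 and 0.0631, and without it edgeR called 5 genes, among them Dtx1 (adjusted p = 0.0187), Il2ra (0.000324) and Ptcra (0.00489). Without IgG ETP 1 or 3 it called 2 or 1.

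Notch target genes were shifted lower by the antibody in ETP (median -0.44, 12 of 15 below 0, camera adjusted p = 1.3e-07, and 0.536 with an estimated correlation), with 0 called by edgeR over all genes, 2 lower by DESeq2 and 3 by edgeR adjusted over the list alone. Myc targets were lower (-0.37, 53 of 58 below 0, 4.98e-13, and an adjusted p = 0.536 with an estimated correlation), with 0 called by edgeR, 2 by DESeq2 and 2 by edgeR adjusted over the list alone. Rrp12, of ribosome assembly, had 37.2 ± 6.36 against 78.7 ± 5.6 CPM (edgeR adjusted p = 0.257), with Nolc1 and Nop56 at -1.12 and -0.60. Mitosis genes (-0.24, 0.0251), such as Ccnb2, Birc5 and Hmmr at -0.51, -0.44 and -0.48, and T-lineage genes (-0.17, 0.00329) were lower and natural killer and innate lymphoid markers higher (0.85, 10 of 10 above 0, 0.00195). With an estimated correlation the adjusted p was 0.827, 0.827 and 0.536 in the same order. No member of these 3 lists passed by either edgeR count or by DESeq2. Cd3g, a chain of the T-cell receptor complex, had 393 ± 185 against 900 ± 127 CPM and Rag1 a log2 fold change of -1.22, while Il1rl1, Id2 and Klrd1 had 1.04, 0.88 and 2.88. Mitosis genes did not pass without AntiNRR ETP 1 (adjusted p = 0.585), AntiNRR ETP 3 (0.623) or IgG ETP 3 (0.959), natural killer markers without AntiNRR ETP 1 (0.166) or IgG ETP 3 (0.0955), and T-lineage genes without AntiNRR ETP 2 (0.349), IgG ETP 1 (0.124) or IgG ETP 2 (0.0742). The other 17 lists did not pass (from 0.118 to 0.841).

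In DN3 the Notch1 antibody changed 710 of 12658 genes in edgeR, 335 up and 375 down, and 934 in DESeq2, 477 up and 457 down. Dtx1 fell 15.4-fold, from 176 ± 17.2 to 11.7 ± 5.82 CPM (log2 fold change -3.94, SE 0.428, adjusted p = 0.00576), Il2ra from 3630 ± 320 to 672 ± 171 (-2.43, SE 0.159, 1.46e-05) and Ptcra from 219 ± 12.2 to 72.9 ± 13.6 (-1.59, SE 0.132, 5.61e-08). Myc (chromosome 15, 61985391 to 61990374, plus strand) fell from 138 ± 37.3 to 69.8 ± 3.15 CPM (-0.99, SE 0.156, 0.000253), and Notch1 itself (chromosome 2, 26457903 to 26516663, minus strand) from 3090 ± 115 to 2130 ± 195 (-0.54, SE 0.0858, 0.000275). Notch3 fell from 1050 ± 24.5 to 613 ± 86.9 CPM and Hes1 from 77 ± 21.2 to 46.3 ± 11.7, while Nrarp (log2 fold change -0.44) did not pass. Other large falls were Mllt4, an adherens junction scaffold (79.8 ± 12.8 to 5.78 ± 2.71 CPM), Arhgef10l, a guanine nucleotide exchange factor (chromosome 4, 140514485 to 140666012, minus strand, 176 ± 7.32 to 15 ± 5.04), Vwce (-2.79) and Rasal1 (-2.57). Among the rises were the mast-cell protease Cpa3 (22.1 ± 7.64 to 128 ± 27.2 CPM), Adra1b (2.45), Lzts1 (2.09), Fndc1 (1.81) and Slc37a3 (1.76).

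**Figure D3:**
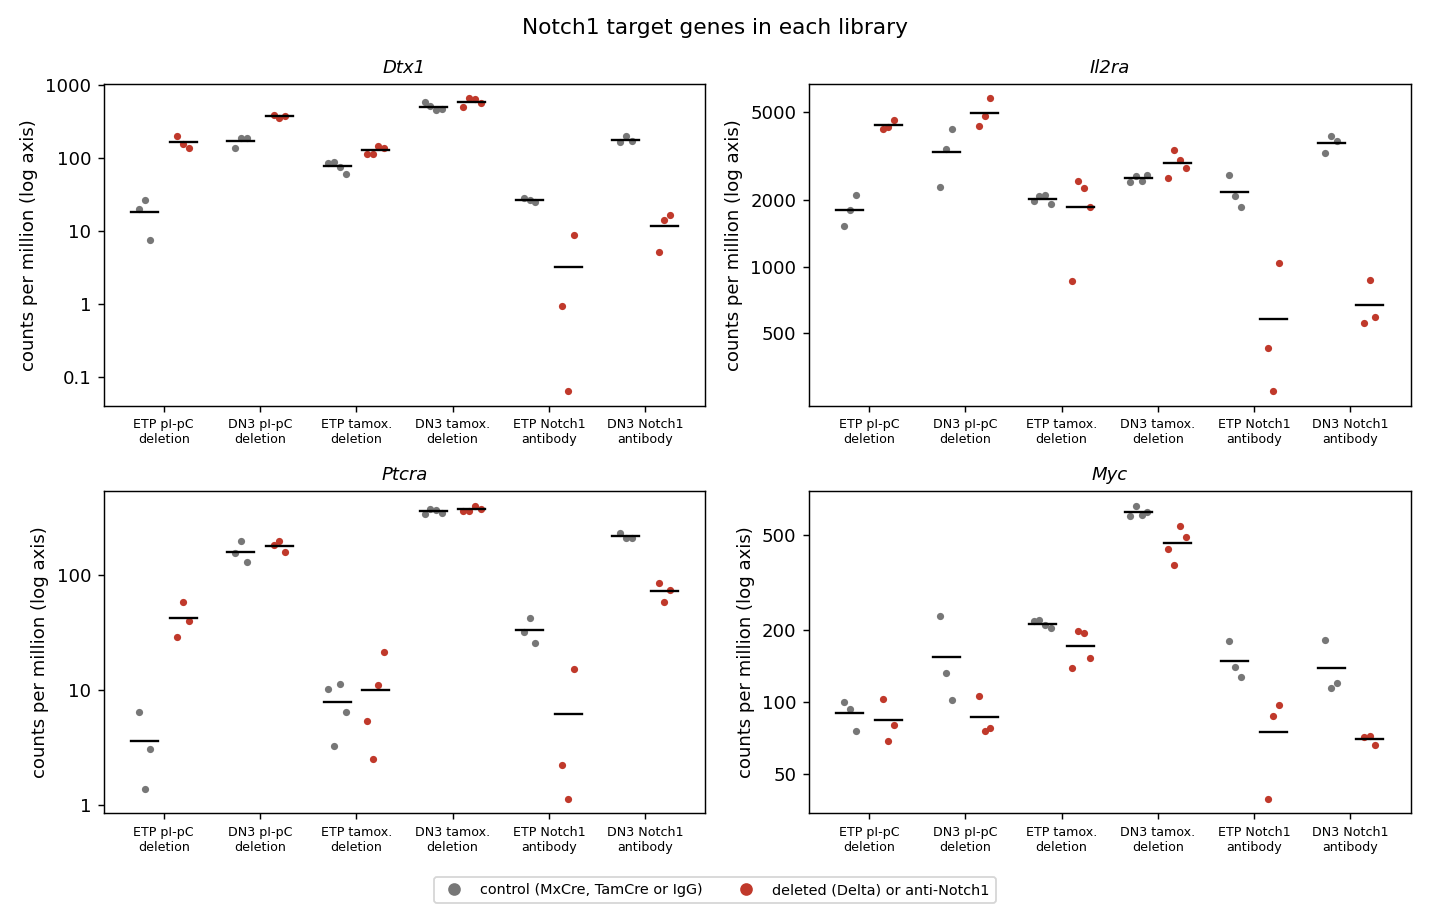
Dtx1, Il2ra, Ptcra and Myc in each library (CPM, log axes) for the 6 comparisons (x axes), with grey points for controls, red points for deleted or antibody-treated libraries and lines at the means. In DN3 all 3 antibody libraries lie below all 3 IgG libraries for each of the 4 genes, and in ETP after pI-pC all 3 deleted libraries lie above all 3 controls for Dtx1, Il2ra and Ptcra.

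Of 16 Notch target genes 7 fell and 1 rose after the antibody in DN3, by both counts (median -0.64, camera adjusted p = 4.59e-11). The riser was Gata3, a T-lineage transcription factor (147 to 255 CPM, chosen after its values were seen). Of 58 Myc targets 23 fell, and 33 adjusted over the list alone (-0.48, 1.3e-19), with Pa2g4, a growth regulator, going from 408 ± 18.6 to 241 ± 15.5 CPM and Mybbp1a and Hspd1 falling by 0.68 and 0.70 on the log2 scale. Both lists passed with an estimated correlation (adjusted p = 0.0454 for each), and they were the only list calls of the 6 comparisons that did. Of 77 ribosomal proteins 8 fell, 12 adjusted over the list alone, and 76 were below 0 (-0.25, 5.28e-11, and an adjusted p = 0.541 with an estimated correlation), with Rpsa, Rpl3 and Rpl35 at -0.39, -0.44 and -0.35. Of 30 S-phase genes 4 fell, 9 adjusted over the list alone (-0.35, 3.06e-07, and an adjusted p = 0.541 with an estimated correlation), among them Uhrf1, of DNA methylation upkeep (810 ± 27.9 to 574 ± 46.8 CPM), Mcm3 (-0.58) and Ung (-1.09). Of 18 glycolysis genes 2 fell by both counts, Hk2 (37.4 ± 4.85 to 12.7 ± 2.5 CPM) and Ldha (-0.35) (list median -0.23, 0.0467, and an adjusted p = 0.541 with an estimated correlation). Rn45s took 5.71 ± 1.02% of counts in AntiNRR DN3 and 3.13 ± 0.536% in IgG DN3.

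Gamma-delta T-cell markers were shifted higher in DN3 after the antibody (median 0.92, camera adjusted p = 3.11e-06, and 0.104 with an estimated correlation), with 3 of 7 risen, 5 adjusted over the list alone, and 1 below 0. The 3 were 5830411N06Rik (65.7 ± 11.4 to 153 ± 34.1 CPM), a scavenger receptor gene, the transcription factor Sox13 (58.3 ± 9.98 to 104 ± 10.6) and Cd163l1 (0.98). p53 targets were higher (0.21, 0.0373, and an adjusted p = 0.279 with an estimated correlation), with 3 of 17 risen by both counts, Trp53inp1 (802 ± 37.8 to 1250 ± 141 CPM), Btg2 (0.48) and the cell-cycle inhibitor Cdkn1a (30.5 ± 0.849 to 52.7 ± 11.7). Immediate early genes were higher (0.34, 0.014, and an adjusted p = 0.541 with an estimated correlation), with 3 of 16 risen by both counts, among them Jund (0.90) and Klf6 (0.90). Double-positive thymocyte markers (0.16, 0.0467, and an adjusted p = 0.279 with an estimated correlation) had 2 risen and 1 fallen of 13, or 3 and 1 adjusted over the list alone, with the chemokine receptor Ccr9 going from 218 ± 26.2 to 630 ± 64.8 CPM, Themis rising by 0.36 and Tox at 0.51 (edgeR adjusted p = 0.0925). The other 12 lists did not pass (from 0.142 to 0.998), among them T-lineage genes, of which 4 rose and 5 fell.

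Without IgG DN3 2 or 3, edgeR called 353 or 351 genes after the antibody in DN3. Of the genes named, several libraries left out singly ended the calls of Hes1, Cd163l1, Cdkn1a, Klf6, Ung, Ldha, Themis, Rpl35 and Adra1b, AntiNRR DN3 1 those of Lzts1 and Rasal1, IgG DN3 2 that of Mcm3 and IgG DN3 3 that of Btg2. A spread shared by all 4 DN3 groups ended those of Myc (edgeR adjusted p = 0.0927), Ccr9 (0.124), Sox13 (0.114), Fndc1 (0.202), Rpsa (0.0788), Mcm3 (0.13), Cd163l1, Klf6, Ldha, Themis, Rpl35 and Adra1b. The p53 shift did not pass without AntiNRR DN3 1 (adjusted p = 0.051), AntiNRR DN3 3 (0.0703) or IgG DN3 1 (0.0642), nor immediate early genes without AntiNRR DN3 1 (0.123), IgG DN3 2 (0.071) or IgG DN3 3 (0.058). Double-positive markers were lost without AntiNRR DN3 1 (0.051), AntiNRR DN3 2 (0.134), IgG DN3 2 (0.071) or IgG DN3 3 (0.058), and glycolysis with DESeq2 size factors (0.0542) or without AntiNRR DN3 1 (0.0618), AntiNRR DN3 2 (0.285) or IgG DN3 1 (0.201).

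**Figure D4:**
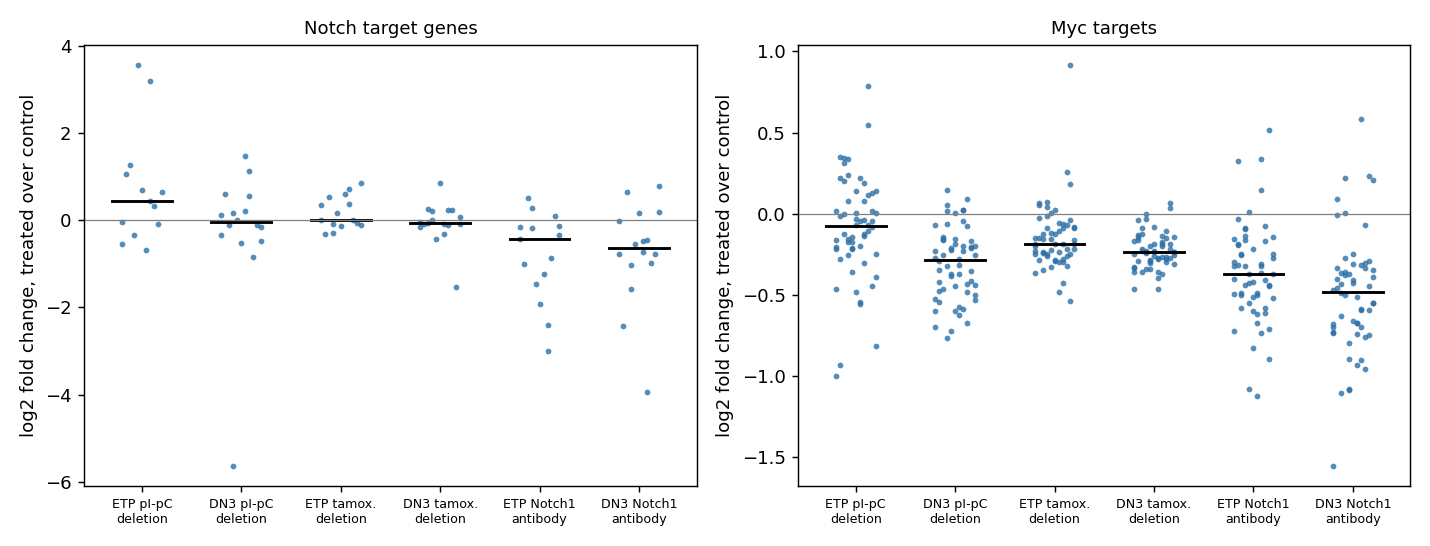
Log2 fold change of each Notch target gene and each Myc target (y axis, 1 point per gene) in the 6 comparisons (x axis), with a black line at the median. The median of the Myc targets lies below 0 in every comparison, from -0.48 in DN3 after the antibody to -0.07 in ETP after pI-pC, where the list did not pass, and with an estimated correlation the list passed only in DN3 after the antibody (adjusted p = 0.0454).

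Several genes differed between the effects of Zmiz1 deletion by pI-pC and of the Notch1 antibody, by the edgeR test of the difference. The deletion libraries were made 8 weeks after pI-pC and the antibody libraries after 24 hours, in separate experiments with their own controls. At both stages, time and experiment therefore cannot be told apart from the loss of Zmiz1 or the block of Notch1 in these differences. In DN3 this difference passed for 167 of 13557 genes (103 higher and 64 lower in the deletion). Dtx1 differed by 5.06 on the log2 scale (1.13 in the deletion, -3.94 after the antibody, adjusted p = 0.000889), Il2ra by 3.01 (0.000961) and Ptcra by 1.73 (1.3e-05). By the lowest p the genes were Bst1 (difference 2.02, effects 0.81 and -1.23, adjusted p = 5.5e-07), Zmiz1 (-1.59), Rn45s (-1.64) and Spats2 (-1.98). Zmiz1 was the deleted gene, so its difference was set by the design. For Myc the effects of -0.84 and -0.99 differed by 0.13 (adjusted p = 0.935), and for Notch1 the difference was 0.52 (0.0757). Without MxCre DN3 3 the count was 290 and without IgG DN3 2 or 3 it was 99 or 101.

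In ETP the difference between deletion and antibody passed for 11 of 13408 genes (8 higher and 3 lower in the deletion). They included the calpain Capn5 (effects 1.33 and -1.07, edgeR adjusted p = 0.00317), Cpa3 (-1.10 and 1.16, 0.00757), Cdh1 (1.92 and -0.45, 0.00757), Bst1 (2.54 and -1.34, 0.0156), Notch1 (0.69 and -0.87, 0.0177) and Il2ra (1.27 and -1.91, 0.0396), while Dtx1 (3.18 and -3.01, 0.338) and Ptcra (3.56 and -2.41, 0.107) did not pass. The call of Bst1 ended without DeltaMxCre ETP 2 or AntiNRR ETP 2, that of Notch1 without any DeltaMxCre ETP library, MxCre ETP 2, AntiNRR ETP 2, IgG ETP 1 or IgG ETP 2, and that of Il2ra without any library but AntiNRR ETP 2 or 3. Without MxCre ETP 1, MxCre ETP 3 or AntiNRR ETP 3 the test called 26, 21 or 17 genes, and without DeltaMxCre ETP 2, AntiNRR ETP 2 or IgG ETP 2 it called 6, 5 or 7.

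Between stages, the effect of pI-pC deletion differed for 1 of 13406 genes in edgeR, Fbln2, an extracellular matrix protein (chromosome 6, 91212455 to 91272540, plus strand, adjusted p = 0.0271). It had 235 counts in DeltaMxCre ETP and 0 in MxCre ETP, at least 90.8-fold higher against 3 counts over the group, and 13.9 ± 1.19 against 12.8 ± 4.63 CPM in DN3. Its call ended without any DeltaMxCre DN3 library, MxCre DN3 2 or MxCre DN3 3. The difference between stages was 3.39 for Ptcra (adjusted p = 0.0652), 2.05 for Dtx1 (0.253), 0.67 for Il2ra (0.866) and 0.74 for Myc (0.918). Without MxCre ETP 1 the test called 12 genes, and without MxCre ETP 3, MxCre ETP 2, DeltaMxCre ETP 1 or MxCre DN3 1 it called 7, 3, 3 or 2. For the antibody, edgeR called 0 of 13603 genes as different between stages (lowest adjusted p 0.887, 743 at an unadjusted p under 0.05, 5 by DESeq2), 3 without AntiNRR ETP 1 and 1 without AntiNRR ETP 2, AntiNRR ETP 3, IgG ETP 1, IgG DN3 1 or IgG DN3 2. The 743 are little above the share of 0.05 that chance alone gives. The tamoxifen effects in ETP and DN3 were not tested against each other.

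Among all genes tested, those whose groups shared no values made up 12.6% in ETP and 21.6% in DN3 after pI-pC and 11.8% and 22.4% after the antibody, where chance gives 10%. They made up 3.99% and 10.2% after tamoxifen, where chance gives 2.86%.

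The calls of the DN3 comparisons overlapped. Deletion by pI-pC and by tamoxifen shared 5 genes that rose, Cd53, Evl, Ggt5, Il31ra and Jakmip1 (0.0718 expected by chance, Fisher's exact test, two-sided, p = 2.16e-09, adjusted over 6 tests 6.48e-09), and 2 that fell, Qsox2 and Zmiz1 (0.0182 expected, p = 0.000121, adjusted 0.000242), with 0 called in opposite directions. Zmiz1 was the gene deleted in both experiments, so its shared fall was set by the design. Qsox2 alone is left as a shared fall, while the p-value counts Zmiz1 too. In both deletions the controls carried the Cre alone, so other differences from the Zmiz1f/f mice could be shared as well and were not tested. Deletion by pI-pC and the antibody shared 19 that rose (3.4 expected, exact p = 1.07e-09, adjusted 6.42e-09), among them Cd53, Jakmip1, Themis and Ms4a4b. They shared 8 that fell (1.76 expected, exact p = 0.000342, adjusted 0.000513), 9930014A18Rik, Csda, Impdh2, Lef1, Nop56, Ptpn13, Rag1 and Rpsa. Another 15 went in opposite directions (5.38 expected), among them Dtx1, Bst1, Fat4, Rn45s and Spats2. Deletion by tamoxifen and the antibody shared 2 that rose, Cd53 and Jakmip1 (0.194 expected, exact p = 0.0147, adjusted 0.0176), and 0 that fell (0.12 expected, exact p = 1), and Gzma was called in opposite directions. The overlaps with tamoxifen rest on 11 edgeR calls after tamoxifen, 4 of them lower, and without TamCre DN3 3 edgeR called 0. Those with pI-pC rest on 183 calls, which fell to 12 without DeltaMxCre DN3 3. By DESeq2 calls tamoxifen deletion and antibody shared 51 genes that rose and 49 that fell (9.34 and 7.59 expected) with 7 in opposite directions (16.8 expected), pI-pC deletion and antibody 54 and 34 (12.2 and 7.62 expected) with 34 opposite (19.6 expected), and the 2 deletions 64 and 28 (6.08 and 3.42 expected) with 0 opposite (9.23 expected). Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.377 and a Spearman correlation of 0.468 between the 2 DN3 deletions, 0.0633 and 0.121 between pI-pC deletion and antibody, and 0.141 and 0.22 between tamoxifen deletion and antibody. In ETP no gene was shared by edgeR calls, 5 after pI-pC and 0 in the other comparisons, and by DESeq2 calls 1 gene was shared between both deletions, the deleted gene Zmiz1 itself, and 1 between pI-pC deletion and antibody, the chaperone Hsph1, with Capn5, Cpa3 and Notch3 called in opposite directions by DESeq2. In simulated data DESeq2 calls held a larger share of unchanged genes than edgeR calls, which limits the overlaps by DESeq2 calls. Of the genes in these overlaps, those outside the naming rule were chosen after their values were seen.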

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

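Tests chosen only after the result was seen were those of DN3 cells (for which the limit was set after the values were known), of fewer cells of other types, of exchanged labels, of library weights, of the Cd8a and Malat1 covariates and of the libraries numbered 1 and 2.

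Among named genes, the highest or lowest library stood far from the other 3 of its group in 5 of 132 groups of 4 libraries, and chance gives about 1 in 20. These were H2-Eb1 in DeltaTamCre ETP 4 (5.83 CPM, others 12.4 to 12.9), Stat2 in TamCre ETP 4 (31.3, others 41.2 to 42.8) and Ier5 in DeltaTamCre ETP 1 (119, others 33.1 to 41.2). The others were Dctpp1 in TamCre DN3 1 (150, others 117 to 122) and Gins2 in TamCre DN3 2 (55.3, others 61.9 to 62.6). No explanation was tested for these libraries. A difference between stages was found for Fbln2 after pI-pC deletion, with a fitted log2 difference of 9.29 that depends on the prior count since all MxCre ETP libraries are at 0 (edgeR adjusted p = 0.0271, up to 0.219 without 1 library). Fbln2 was present in both DN3 groups. DN3 cells among the sorted ETP, weighed below for 5 other genes, could therefore bring it, and this was not tested for Fbln2.

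In ETP after pI-pC, Dtx1, Il2ra, Ptcra, Bst1 and Cdh1 rose. DN3 cells among the sorted ETP (their gate is CD44-positive and CD25-negative in the labels, which would remove CD25-bearing cells, but DN3 are labelled so too) would bring the other DN3 transcripts, and 66 genes high in DN3 put the share of DeltaMxCre DN3 RNA at a median of 9.28, 20.8 and 24.1% and a 95th percentile of 58.5, 72 and 82.2% in the 3 deleted libraries. Il2ra needs at least 90.5%, above that percentile in all 3, so DN3 RNA alone is argued against for Il2ra, while Dtx1, Bst1, Cdh1 and Ptcra need at least 37.3, 31.4, 53 and 16.3%, within the spread of single genes in 1 library or more, and for them it cannot be told apart from a change within ETP. The 66 genes were at least 4-fold higher in DeltaMxCre DN3 than in MxCre ETP. Il2ra differed less, at 4730 against 1920 CPM in a joint scaling, so its share is less sharply set. RNA of other CD25-bearing cells was not modelled, and for Il2ra it was not tested. Fewer cells of other types would raise T-lineage genes alike, yet without Ptcra their 95th percentile was 0.693 (1 of 23, Rag1, above Il2ra) against 1.27 for Il2ra, the smallest rise of the 5, which argues against it as the whole source. A response to the loss of Zmiz1 within ETP stays open beside it, as a hypothesis found in these data.

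In DN3 after tamoxifen, edgeR called 11 genes and the library-weighted test 1047. Exchanging DeltaTamCre DN3 2 with TamCre DN3 2 called 936 genes, none of the 11 among them, with Cd4 and Cd8a higher by 2 and 1.8 (log2), which points to a structure of the samples beside the groups. Exchanged labels are argued against, since DeltaTamCre DN3 2 scored 0.485 above the highest TamCre library over 178 genes called after pI-pC, and no single library was the source, as leaving out 1 gave at most 8 calls. Without the libraries numbered 1 and 2 of both groups 2551 genes were called, but the libraries left lie on opposite sides of Cd8a by group, so added spread from those libraries cannot be told apart from that structure. Cells with Cd4 and Cd8a (the sort was Lineage-negative, a gate that would remove them if its markers, which the labels do not list, held CD4 and CD8), a batch that the labels do not give and a biological change in passage to later stages stay open and untested.

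In DN3 after pI-pC, 183 genes were called while Malat1 and Rn45s differed between the groups. Scaling moved by Rn45s is argued against, since without ribosomal RNA genes 100% of the other 182 called genes were called again in the same direction. Within groups the called genes followed Malat1 in the direction of their change (median signed correlation 0.281, against a 95th percentile of 0.118 over 1000 random sets), so RNA quality or nuclear RNA content may contribute to the calls. Random sets lack the correlation among the called genes, which makes this limit narrow, and the correlations rest on 3 libraries per group. Whether the calls follow Malat1 is thus not settled. With Malat1 as a covariate 116 genes were called, 34 of them shared with the 183, a fit in which Malat1 and the groups are partly confounded. A biological change of Malat1 itself after the loss of Zmiz1 stays open and untested.

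With 3 libraries against 3, other splits of the libraries are too few for a share under 0.05. The real split called 5 genes in ETP after pI-pC (highest other 4), 183 in DN3 after pI-pC (highest other 0) and 710 in DN3 after the antibody (highest other 1). Where edgeR called 0 genes every split reaches that count by construction, so the splits say nothing about chance. This holds for ETP after the antibody (all 10 splits, highest other 9, with 687 genes at an unadjusted p under 0.05 and 28 by DESeq2), ETP after tamoxifen (all 35, highest other 0, with 640 and 2) and the difference between stages after the antibody (all 100, highest other 244, with 743 and 5). The unadjusted counts are at or little above the share of 0.05 of the genes tested that chance alone gives. In DN3 after tamoxifen the splits do not exclude chance for the count, since 2 of 35 splits called at least 11 and the highest other called 936. For genes shared with DN3 after pI-pC, which has other libraries, the values argue against chance alone. Of 7 genes that rose 5 rose there too (0.0718 expected), with 0 in opposite directions. Both deletions compared Zmiz1f/f mice carrying a Cre with mice carrying the Cre alone. Sharing therefore does not tell the deletion from other differences between these mice. Over 178 genes called after pI-pC, DeltaTamCre DN3 libraries scored 0.284 to 0.742 and TamCre ones -0.851 to -0.201, a test chosen after the result was seen. For the difference between stages after pI-pC chance is not excluded either, with 1 gene called (21 of 100 splits called as many, the highest other 113). The splits with 113 and 244 calls keep or mirror the groups of an experiment and so carry its real effects. For the differences between deletion and antibody, few splits called as many genes as the real one. These were 1 of 100 in ETP (11 genes, highest other 3) and 2 of 100 in DN3 (167 genes), where the other one called 897 by mirroring the antibody groups, which adds the effects. Most splits mix the groups of both experiments and so take away both effects, not only their difference. In DN3, splits that kept or mirrored the antibody groups but mixed the deletion groups called 6 to 92. The splits therefore cannot exclude chance for a difference between 2 real effects.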

How the results depend on the processing

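Library weights, the Cd8a and Malat1 covariates and leaving out the libraries numbered 1 and 2 were chosen after the data were seen, and the other alternatives before. Over 267 named-gene results 4273 alternative values were computed. Of these 3819 kept their side of the threshold, 284 no longer passed, 170 newly passed and 0 reversed. A reversal was counted only where the main or the alternative value passed. A change of direction with neither passing was counted among those that kept their side. Over 50 list results there were 555 values, counted in the same way. Of these 410 kept their side of the threshold, 138 no longer passed, 1 newly passed and 6 reversed. Of 245 values of 22 counts 149 stayed within 1.5 times and 96 moved. Except where stated, the cause was not tested.

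The counts of genes called (5, 183, 0, 11, 0 and 710, in the order ETP pI-pC, DN3 pI-pC, ETP tamoxifen, DN3 tamoxifen, ETP antibody, DN3 antibody) moved with DESeq2 to 86, 527, 2, 458 and 28 in the first 5. With no filter they were 18 and 347 after pI-pC and 8 in ETP after the antibody, and with a spread shared by 4 groups 399 in DN3 after pI-pC. Against a fold of 1.2 they were 1, 63, 2 (DN3 tamoxifen) and 240 (DN3 antibody), where a stricter null is tested. Voom with library weights gave 19, 358, 1047 (DN3 tamoxifen) and 3 (ETP antibody). A replicate block gave 14 in ETP after pI-pC, 0 in DN3 after tamoxifen by edgeR (2069 at an unadjusted p under 0.05 without the block, 458 by DESeq2) and 0 for the difference between stages after pI-pC, which ends the call of Fbln2. The labels do not say that a number marks a mouse. Same-numbered libraries of the groups compared had correlated deviations from -0.639 to 0.233, and those of the same group at both stages from -0.00788 to 0.342 after pI-pC and from -0.122 to 0.0106 after the antibody. No comparison had every pair over 0.1 or every library closest to its own number, so the numbers are not shown to pair libraries, and shared mice across stages are not excluded. Malat1 as a covariate gave 116 in DN3 after pI-pC and lacking libraries 1 and 2 gave 2551 in DN3 after tamoxifen. Differences moved with DESeq2 from 1 and 0 (between stages, pI-pC and antibody) to 50 and 5, and from 11 and 167 (deletion against antibody, ETP and DN3) to 80 and 344.

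Lists called (10, 9, 6, 7, 5 and 9) fell to 0 with an estimated correlation in camera in the first 5 comparisons and to 2 in DN3 after the antibody. With fry they were 2, 0, 0, 4 and 0 in the first 5. Shared calls moved to 1 with DESeq2 for ETP pI-pC with antibody and with tamoxifen. In DN3 they moved, at an adjusted p under 0.1 and with DESeq2, to 77 and 88 (pI-pC and antibody), 6 and 100 (tamoxifen and antibody) and 14 and 92 (pI-pC and tamoxifen).

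With 1 library left out, genes called ranged from 0 to 17 (ETP pI-pC), 12 to 403 (DN3 pI-pC), 0 to 1 (ETP tamoxifen), 0 to 8 (DN3 tamoxifen), 0 to 5 (ETP antibody) and 351 to 677 (DN3 antibody). Differences between stages ranged from 0 to 12 (pI-pC) and 0 to 3 (antibody), and between deletion and antibody from 5 to 26 (ETP) and 99 to 290 (DN3). Lists called ranged from 8 to 12, 6 to 10, 3 to 8, 6 to 10, 4 to 8 and 6 to 9. Directions reversed, none past the threshold, for ribosomal proteins in ETP after pI-pC without MxCre ETP 3 (mean log2 fold change -0.00166, with camera's direction up, range -0.27 to -0.00166), S phase in DN3 after pI-pC without MxCre DN3 3 (0.056, range -0.342 to 0.056), immediate early genes in ETP after tamoxifen without DeltaTamCre ETP 1 (-0.517, range -0.517 to 0.856) and mitosis in ETP after the antibody without IgG ETP 3 (0.166, range -0.793 to 0.166). With Malat1 as a covariate in DN3 after pI-pC, S phase (0.504, camera adjusted p = 6.99e-09) and glycolysis (0.0529, adjusted p = 0.4) reversed. Total counts ran from 9456818 per library, and genes below the count filter were not tested, which is a limit for genes of low level.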

Other observations

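The test of a Cd4 and Cd8a axis was chosen, and the limit of the Myc target test set, only after the result was seen. Genes that the Notch1 antibody lowered in DN3 were lower on average after both deletions too. Of 373 such genes tested after pI-pC 281 were below 0 (median log2 fold change -0.225), and of 363 after tamoxifen 276 were (-0.171). Over all genes tested in DN3 the medians were -0.0145 after pI-pC and 0.0117 after tamoxifen. Malat1 differed between the DN3 groups after pI-pC, and these genes were not tested with it as a covariate. The hypothesis that the loss of Zmiz1 lowers the genes that Notch1 maintains in DN3 was tested with camera and an estimated correlation between genes, and gave p = 0.193 after pI-pC and p = 0.0566 after tamoxifen, so it stays open. Dtx1, Il2ra and Ptcra, which the antibody lowered, had log2 fold changes above 0 in both DN3 deletions, where the rises of Dtx1 (edgeR and DESeq2) and Il2ra (DESeq2 alone) after pI-pC passed.

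The values argue against the listed Myc targets as the whole source of this shared fall, since genes outside the list were lower too. Whether Myc targets that are not on the list carry it stays open. Outside the Myc target list the median was -0.218 over 350 genes after pI-pC, 73.7% of them below 0, and -0.161 over 340 genes after tamoxifen, 74.4% below 0. Within the list the 23 genes had lower medians, -0.347 and -0.277, and a list of 58 genes leaves out other Myc targets, so genes outside it do not exclude Myc. Whether a Cd4 and Cd8a axis across the DN3 tamoxifen libraries is the whole source of the lower Myc targets is not settled. With Cd8a as a covariate their mean log2 fold change went from -0.226 to -0.159. It stayed below 0, and the list still passed camera with the preset correlation (adjusted p = 3.49e-11). With an estimated correlation the list did not pass camera even without the covariate (adjusted p = 0.176), so this pass cannot decide the question. Part or all of the fall may still follow the axis. Genes are not independent replicates, and the same libraries raised and tested both hypotheses.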
